A study of Homo sapiens with 4 samples.

How the data were processed

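Polyadenylated RNA of 4 leukaemia cell lines (K562, THP-1, MOLM13 and HL-60) was sequenced, 1 library per line. Per the labels' protocols the RNA was captured on oligo-dT beads and primed with random hexamers. Per the submitters' processing notes, reads were handled with fastp and aligned with HISAT2 2.2.1 to GRCh38 (hg38). Expression was estimated with StringTie 2.1.5 per the file headers, restricted to the transcripts of GENCODE v28. No strand option was set, so reads of overlapping genes on opposite strands may not be fully told apart. For every transcript the authors deposited the coverage (mean reads per base, not normalized), the FPKM (coverage divided by a single factor per library) and the TPM (coverage scaled so that all transcripts of a library sum to 1e6); for every exon they deposited coverage only. Read counts were not used here. The files do not state aligner settings or filters.

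Each file held 203835 transcripts and 1237200 exons of 58381 genes. Gene TPM was the sum over a gene's transcripts. Names and coordinates (GRCh38) are those of the files. Gene classes came from GENCODE v29, matched on the identifier without its version: 58261 of 58381 genes matched, giving 19881 protein-coding, 15696 lncRNA and 22804 other genes. The total of aligned bases followed from the ratio of coverage to FPKM, and its quotient by the most frequent read length, 150 nucleotides, gave read equivalents: 54.5 for K562, 53.1 for THP-1, 57.7 for MOLM13 and 62.3 for HL-60, in units of 1e6 reads. On a 1-kb transcript 1 TPM stood for 21.4 to 27.0 of these. Intervals on coverage ratios came from read equivalents as Poisson counts and cover counting error only, since reads without molecular identifiers are not independent molecules. An exact 0 in an estimate can be a failed fit, so such values are described as listed at 0 and no size of a fold is printed against them; the enriched and depleted counts and the list medians, taken on TPM + 1, do include them.

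The following choices were made before the data were examined. A gene was detected at 1 TPM in at least 1 line. It was enriched in a line at 10 TPM or more and at least 4-fold above the highest other line, and depleted at least 4-fold below the lowest other line where that had 10 TPM or more, both on TPM + 1. The lines were compared by Spearman and Pearson correlation across detected genes of log2(TPM + 1). For 29 gene lists (653 entries, of which 637 were found in the files) the median over detected members of the log2 difference from the mean of the other 3 lines was set against 10000 random lists of the same size, matched on mean expression in 20 bins; 28 lists had the 5 detected members this needs. A median outside the middle 95% of random lists is described as outside the range, which is a statement on these libraries and not a test of the lines. The differences of a gene cancel out over the libraries, so a list's medians in different libraries are not separate results. The share of lncRNA genes enriched was set against random sets of coding genes matched on the highest TPM, with exact (Clopper-Pearson) 95% intervals.

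For the partners of known fusions, the mean exon coverage of the later exons was divided by that of the earlier ones (ABL1 exons 2 onward by exon 1, BCR exons 15 onward by 1 to 13, KMT2A exons 13 onward by 1 to 7, MLLT3 exons 7 onward by 1 to 4, numbered along the longest transcript). A gene at 10 TPM or more in all lines was counted as switching transcript where the transcript with the highest share differed and some share differed by at least 50 points. Silent runs were 3 or more neighbouring coding genes under 0.5 TPM in a line among those at 5 TPM or more in at least 1 line, beside 1000 shuffled gene orders. Regional windows held 25 neighbouring detected coding genes. No p-value was computed, since each line has 1 library and genes are not replicates.

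The genes named were fixed by rule. Per line they were the 8 coding and 4 lncRNA genes most enriched and the 4 most depleted. These left out clone names, read-through genes, mitochondria, chromosome Y and XIST. Up to 4 members of each list at 10 TPM or more with the widest range were named. So were any leukaemia driver or HOX lncRNA at any level, and any dual-function lncRNA at 10 TPM. The 6 genes with the largest transcript shift, the fusion partners and the 3 highest genes per library were named too. Genes of the 2 longest silent runs and up to 5 of each extreme window per line completed the named genes. Others are marked as chosen after their values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

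Each step was tested on simulated data, in which the libraries shared a common expression profile with little noise. Genes not planted could hardly pass the fold rules there, so those counts check the code and not the rate of false calls. Among 58381 genes, planted 6-fold and 10-fold enriched genes were all recovered (33 of 33 at each size), 0 of 34 planted at 3-fold were called, and no other gene was; depleted genes gave the same numbers. A list planted at 2-fold left the random range, as did 1 of 40 lists left alone (13853 genes). All 60 lncRNA genes planted at 8-fold were recovered (1593 genes), as were 100 of 100 exchanged transcripts (8072 genes), 20 of 20 silent runs of 5 genes (8966 genes), a planted window (10766 genes) and a coverage ratio of 0.25. Alternatives were the pseudocount, the TPM minimum, the fold threshold, FPKM, median-ratio scaling, rescaling over coding genes, other detection limits, other sizes of runs, windows and share differences, and leaving out each comparator line in turn. 3 more were added after the data were seen: comparators without both the libraries labelled THP-1 and MOLM13 (for enriched and for depleted genes), and the lncRNA share without the library labelled THP-1. Median-ratio factors were 1.03, 1.05, 1.16 and 0.847 for K562, THP-1, MOLM13 and HL-60, and moved the median log2 difference over all detected genes from 0.01, 0.03, 0.16 and −0.36 to −0.01, −0.02, −0.05 and −0.09. Class II antigen presentation was the list without a percentile. Results for a few withheld genes are not reported here. Fusion reads, junctions, variants and genome sequence were not available.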

Results

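RNA was sequenced from 4 established human leukaemia cell lines, K562, THP-1, MOLM13 and HL-60, with 1 library per line, after capture of polyadenylated RNA on oligo-dT beads. K562 comes from a chronic myeloid leukaemia in blast crisis and is known for erythroid traits and the BCR-ABL1 fusion; THP-1 is monocytic and MOLM13 is a monocytic acute myeloid leukaemia line, and both are known for the KMT2A-MLLT3 fusion; HL-60 is promyelocytic. The series title names the identification of long non-coding RNAs (lncRNAs) with more than one function, and the libraries show which lncRNAs and coding genes each line expressed. With 1 library per line no difference below has a replicate check, and each is a property of these libraries. Per the labels K562 and HL-60 grew in the same medium and the others each in their own. The medium named thus does not separate K562 from HL-60, but for the others medium and line cannot be told apart. The files gave 8.18 Gb of aligned bases for K562, 7.97 Gb for THP-1, 8.66 Gb for MOLM13 and 9.34 Gb for HL-60. In units of 1e6 reads of 150 nucleotides these equal 54.5, 53.1, 57.7 and 62.3, and 1 TPM on a 1-kb transcript stood for 24.6, 21.4, 23.6 and 27.0 reads in the same order. At 1 TPM or more, 15142, 14920, 15135 and 13586 genes were listed, of which 2015, 1970, 2088 and 1528 were lncRNA genes. The union over the lines was 19194 detected genes. lncRNA genes held 2.24%, 2.27%, 1.87% and 1.38% of all TPM, and mitochondrial genes 16.0%, 14.8%, 19.3% and 20.4%. The highest nuclear genes were the translation elongation factor EEF1A1 (8384 TPM), RPS18 (4517 TPM) and RPS2 (4245 TPM) for K562. For THP-1 they were EEF1A1 (7470 TPM), CTD-2643I7.4, a gene model that spans the fetal globin genes (5936 TPM), and the ferritin light chain FTL (4684 TPM). For MOLM13 they were the actin gene ACTB (6103 TPM), EEF1A1 (4525 TPM) and GAPDH (3258 TPM), and for HL-60 myeloperoxidase MPO (11558 TPM), EEF1A1 (8413 TPM) and ACTB (7545 TPM).

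The first question was how alike the lines were. The library labelled THP-1 was close to the K562 library and carried the K562 library's erythroid genes, fetal globins included, with low levels of monocyte genes. The Spearman correlation across the 19194 detected genes was 0.942 for this pair, against 0.717 to 0.800 for the other 5 pairs, with MOLM13 and HL-60 next at 0.800; genes are not independent replicates. Of the detected genes, 13.02% differed at least 2-fold between K562 and THP-1, and 34.6% to 40.1% did so in the other pairs. At least 4-fold above both other lines stood 518 genes for the pair of K562 and THP-1, 226 for MOLM13 and HL-60, and between 3 and 14 for each other pair. The libraries were still not copies of each other: of 9562 genes at 10 TPM or more in K562 or THP-1, 1055 were at least 2-fold apart and 196 at least 4-fold. Known traits of the lines thus contradict the label THP-1, and the low FLT3 and monocyte list values described further down leave the label MOLM13 in doubt. Both are therefore named as the libraries labelled THP-1 and MOLM13, and wherever a direction is drawn for them it is that of the library, which need not be that of the line. CD14 and LYZ, monocyte genes chosen after their values were seen, were listed at 0.20, 0.19, 0.29 and 13.05 TPM and at 32.4, 11.98, 0.24 and 145 TPM in K562, THP-1, MOLM13 and HL-60.

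Among what these 2 libraries shared was an erythroid programme. Of the 27 detected erythroid genes, 21 were at least 2-fold above the mean of log2(TPM + 1) in the other 3 lines in K562 and 24 in the library labelled THP-1, with median log2 differences of 2.30 and 3.59; in that labelled MOLM13 and in HL-60, 20 and 24 genes were at least 2-fold lower, with medians of −2.41 and −3.86. In the library labelled MOLM13 4 of the erythroid genes were at least 2-fold higher, and in HL-60 0 were. All 4 medians lay outside the middle 95% of 10000 random lists matched on expression. They are not 4 separate results, since each library is set against the others. The fetal gamma-globin HBG2 was listed at 2630 TPM in K562 and 3954 TPM in the library labelled THP-1, HBG1 at 1571 and 3061 TPM, and the alpha-globin HBA1 at 1025 and 2109 TPM, against 0.10 TPM for HBA1 in the library labelled MOLM13 and 0 for all 3 in HL-60. Embryonic epsilon-globin HBE1 was higher in K562, at 3447 TPM against 181 TPM. HBG1, HBG2 and CTD-2643I7.4 share sequence or overlap, as do HBA1 and HBA2, so the split between them is uncertain. The erythroid transcription factors GATA1 and KLF1, chosen after their values were seen, were listed at 343 and 182 TPM in K562 and at 183 and 102 TPM in the library labelled THP-1. The 14 genes of haem synthesis lay inside the random range for every line, with medians of 0.01, 0.25, 0.19 and −0.51 for K562, THP-1, MOLM13 and HL-60. ALAS2, the erythroid enzyme that starts the pathway, was nonetheless listed at 13.7 and 20.0 TPM in the first pair and at 0.074 and 0.17 TPM in the others, and UROD, a later enzyme, at 624, 681, 164 and 109 TPM.

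Germline antigens, the HOXB cluster, epithelial genes and stress-response genes were also shared by K562 and the library labelled THP-1. Of 15 detected cancer-testis genes, normally confined to germ cells, 12 and 9 were at least 2-fold higher (medians 4.27 and 2.25), and 12 were lower in each of the libraries labelled MOLM13 (−2.88) and HL-60 (−2.51). PRAME, a tumour antigen, reached 1660 and 1600 TPM in the first pair against 0.16 TPM in the library labelled MOLM13 and 69.6 TPM in HL-60; MAGEA3 (174 and 167 TPM) and MAGEA6 (131 and 148 TPM) were listed at 0 in the others. All 9 HOXB genes, which set positional identity and are active in blood progenitors, were at least 2-fold higher in K562 and 8 in the library labelled THP-1, with medians of 2.80 and 2.32 against −2.13 and −2.91. HOXB9 was listed at 142, 159, 5.48 and 0 TPM in the order K562, THP-1, MOLM13, HL-60, HOXB3 at 50.9, 35.1, 6.29 and 0 TPM, and HOXB2 at 76.0, 64.4, 63.6 and 0 TPM. Among 6 detected genes of the stromal, epithelial and endothelial list (medians 4.80, 3.87, −4.33 and −4.33), the keratins KRT8 (366 and 204 TPM), KRT18 (325 and 278 TPM) and KRT19 (131 and 81.3 TPM) and the adhesion protein EPCAM (99.3 and 60.1 TPM) were high in the first pair and no higher than 0.50 TPM in the others. Immediate-early and stress genes had medians of 1.31, 0.91, −1.07 and −0.76 over 22 genes, all outside the random range; without K562 among the comparators the HL-60 value was −0.22 and inside it. The growth-response factor EGR1 was listed at 133, 77.3, 0.59 and 11.8 TPM and the heat-shock gene HSPA1A at 164, 231, 7.56 and 9.55 TPM.

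**Figure D1:**
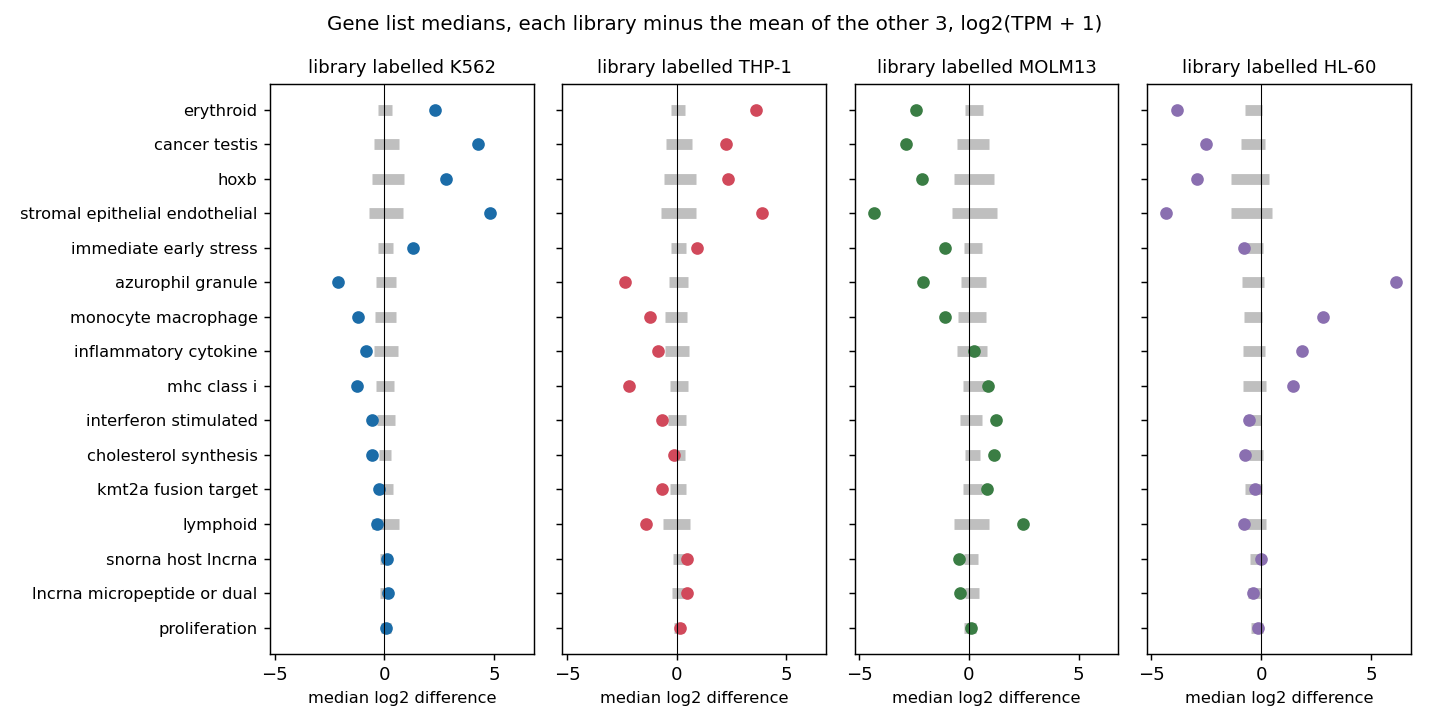
Median over each gene list's detected members of the log2 difference from the mean of the other 3 libraries, on TPM + 1 (x axis, points), for a selection of the 29 lists (y axis) in the 4 libraries as labelled; grey bars give the middle 95% of 10000 random lists matched on expression. The erythroid list lies at 2.30 and 3.59 in the libraries labelled K562 and THP-1 and at −2.41 and −3.86 in those labelled MOLM13 and HL-60.

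Genes that set each line apart were then counted, as those at 10 TPM or more and at least 4-fold above every other line. K562 had 51 such genes (33 coding, 10 lncRNA), and the largest ratios belonged to germline antigens, epsilon-globin and an imprinted lncRNA locus. CTAG2, a cancer-testis antigen, was listed at 184 TPM and at 0 elsewhere. XAGE1B (34.6 against 0.38 TPM in the library labelled THP-1), XAGE1A (31.9 against 0.36 TPM) and GAGE12J (87.1 against 3.56 TPM) are further germline antigens, near-identical copies whose reads cannot be fully told apart. The homeobox gene TLX1, known from T-cell leukaemia, had 24.7 TPM, the vascular phosphatase PTPRB 22.5 TPM and PLBD1 14.2 TPM. The maternally expressed lncRNA MEG3 (chromosome 14, 100779410 to 100861031) had 680 TPM against 32.3 TPM in the library labelled THP-1 and 0 in the others, and its neighbour MEG8 34.0 against 2.098 TPM. TSPEAR-AS2 had 10.1 TPM. ABALON had 22.4 TPM, yet it lies opposite BCL2L1, a survival gene at 209 TPM in K562, and without a strand option their reads may not be fully separated. Only 6 genes were at least 4-fold below every other line in K562, among them PTPRC, the pan-leukocyte phosphatase CD45, at 1.86 TPM against 69.8 TPM or more, the carbonic anhydrase CA2 at 0.33 against 10.1 TPM or more, ARHGAP4 at 4.46 and the acetate enzyme ACSS1 at 2.15 TPM.

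For the library labelled THP-1 the count was 54 (30 coding, 15 lncRNA), led by another germline antigen and an olfactory receptor gene inside the globin locus. MAGEA1 was listed at 80.1 TPM and at 0 elsewhere. OR51B5 (chromosome 11, 5303444 to 5505652) had 415 TPM against 7.52 TPM in K562 and 0 elsewhere; its span overlaps HBG2 and HBE1 on the same strand. RELN, an extracellular matrix protein of the developing brain, had 30.02 against 0.24 TPM in K562. The retinal dehydrogenase ALDH1A1 had 37.7 TPM against at most 2.21 TPM, CILP2 24.2 TPM, the glycogenin GYG2 19.6 TPM, the choline-transporter-like gene SLC44A4 17.7 TPM and the homeobox gene NKX6-3 13.6 TPM. None of its 15 lncRNAs has a name other than a clone name. At least 4-fold below every other line were 15 genes. The granule proteoglycan SRGN had 2.24 TPM against 69.5 TPM or more, the myeloid peptidase ANPEP (CD13) 0.53 against 26.3 TPM or more, and MAGED1 0.55 against 21.3 TPM or more. Each of these 2 counts depended on the other library: without the library labelled THP-1 among the comparators K562 had 701 enriched and 277 depleted genes, and without K562 that labelled THP-1 had 697 and 285. On FPKM, with the same minimum and pseudocount, the 2 enriched counts were 29 and 17. FPKM values ran below TPM in each library, so this is a stricter limit.

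In the library labelled MOLM13, 436 genes (370 coding, 42 lncRNA) stood at least 4-fold above every other line. CRISP3, a granule protein, had 776 TPM, the cytotoxic-cell protease CTSW 625 TPM, HDC, which makes histamine, 497 TPM, the interleukin-33 receptor IL1RL1 358 TPM, PCDH10 310 TPM, the progenitor marker CD34 297 TPM, the scavenger receptor STAB1 273 TPM and GCSAML 172 TPM. None of these 8 exceeded 1 TPM in another line. The named lncRNAs were KIAA0125, also called FAM30A and known from blood stem cells (108 TPM), HOXA-AS4 (63.7 TPM), KIAA0087 (26.1 TPM) and C20orf200 (23.5 TPM); HOXA-AS4 lies opposite HOXA9 and HOXA10. At least 4-fold below every other line were 96 genes. The neuropeptide galanin GAL was listed at 0 against 163 TPM or more, the tetraspanin CD81 at 0.076 against 146 TPM or more, the protease inhibitor CST3 at 0.052 against 124 TPM or more and the deubiquitinase USP22 at 0 against 71.4 TPM or more. Without HL-60 among the comparators the counts were 782 and 663.

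Several fixed lists stood out in the same library. Of 26 interferon-stimulated genes, which respond to viral infection, 18 were at least 2-fold higher (median 1.22), with medians of −0.57 in K562 and −0.68 in the library labelled THP-1, both below the range, and −0.54 in HL-60, inside it; the HL-60 value was 0.24 and above the range without the library labelled MOLM13. RSAD2 had 92.4 TPM against at most 3.76 TPM, IFI44 36.4 against at most 0.49 TPM and IFI6 37.7 against at most 15.1 TPM, while IFITM1 was listed at 594, 643, 355 and 10.2 TPM. Lymphoid genes had a median of 2.45 over 12 genes, against −0.34 in K562, −1.40 in the library labelled THP-1 and −0.78 in HL-60, of which only the THP-1 value lay outside the range. The T-cell receptor subunit CD3D reached 536 TPM (118 TPM in K562), CD7 120 TPM, the surrogate light chain IGLL1 60.6 TPM and the cytotoxic granule protein NKG7 59.7 TPM. Of 20 genes of cholesterol synthesis, 13 were at least 2-fold higher (median 1.13), with medians of −0.54 in K562 and −0.75 in HL-60, both below the range, and −0.10, inside it, in the library labelled THP-1. SC5D, a late enzyme of the pathway, was listed at 11.6, 16.6, 83.7 and 19.2 TPM and LSS at 77.9, 56.0, 136 and 20.4 TPM. Targets of KMT2A fusions had a median of 0.81 over 27 genes, 13 of them at least 2-fold higher and 3 lower, against −0.25, −0.66 and −0.27 in K562, THP-1 and HL-60, of which only the THP-1 value lay outside the range, below it. The leukaemic homeobox gene HOXA9 had 139 TPM, HOXA10 55.4 TPM and HOXA7 48.7 TPM, and each had at most 2.11 TPM elsewhere. HOXA3 was listed at 13.8, 2.39, 22.5 and 0 TPM. MEIS1, the partner of HOXA9 on DNA, was listed at 0 in the library labelled MOLM13, which can be a failed estimate, and at 6.25 TPM in K562 (a gene chosen after its values were seen).

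Of 11 megakaryocyte and platelet genes the median was −0.15 in the library labelled MOLM13, 0.08 in K562, −0.89 in HL-60 and −0.71 in the library labelled THP-1, the last below the range. The median hid members that went both ways. With the 6 members at 10 TPM or more in at least 1 library it was 4.47 in the library labelled MOLM13. Members could pass that minimum by being high in this library, so the rise can follow from the choice of members. ITGA2B, the platelet integrin CD41, was listed at 22.97, 4.18, 343 and 3.13 TPM in the order K562, THP-1, MOLM13, HL-60, the platelet kinase substrate PLEK at 0.086, 0.097, 446 and 124 TPM, and the transcription factor FLI1 at 0, 0, 103 and 43.9 TPM. GP1BB, part of the von Willebrand factor receptor, went the other way, at 92.3, 97.6, 2.97 and 0 TPM. Stem and progenitor surface genes had medians of −0.36, −1.30, 0.30 and 1.23 over 13 genes, below the range in the library labelled THP-1 and above it in HL-60. CD34 aside, CD96 had 216 TPM in the library labelled MOLM13 and at most 1.24 TPM elsewhere, CD38 135 TPM there and 31.1 TPM in HL-60, and the myeloid lectin CLEC12A 71.5 TPM in HL-60 and at most 0.47 TPM elsewhere.

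HL-60 had 262 enriched genes (234 coding, 14 lncRNA), and those with the largest ratios included granule proteins. MPO had 11558 TPM, the granule proteases PRTN3 1023 TPM and ELANE 907 TPM, the calcium-binding proteins S100A9 590 TPM and S100A8 299 TPM, the nuclear antigen MNDA 271 TPM, BASP1 223 TPM and CD4 210 TPM. Outside HL-60 none of these 8 exceeded 1.64 TPM. The named lncRNA was FAM201A at 21.9 TPM, opposite ANKRD18A. Of 20 azurophil granule genes 19 were at least 2-fold higher (median 6.13, against −2.09, −2.36 and −2.09 in K562, THP-1 and MOLM13), and SRGN reached 7501 TPM. Late neutrophil granule genes had medians of −1.56, −1.70, −0.70 and 2.26 over 9 genes, the third inside the range. CHI3L1 was listed at 185 TPM, CEACAM6 at 58.9 TPM and the granulocyte growth factor receptor CSF3R at 44.7 TPM in HL-60; CSF3R had 45.4 TPM in the library labelled MOLM13. Of 23 monocyte and macrophage genes, 19 were higher in HL-60 (median 2.83), and the medians were −1.21, −1.24 and −1.07 in K562, THP-1 and MOLM13. The 7 genes of the NADPH oxidase, which makes the respiratory burst, had medians of −1.27, −1.37, −0.55 and 3.20, the third inside the range, with NCF4 at 174 TPM, CYBB at 174 TPM and NCF1 at 162 TPM in HL-60. The low values of these 4 lists in the other libraries depended on HL-60 as a comparator. Without it each lay inside the range, and the azurophil and monocyte medians in K562 and the library labelled THP-1 were 0 to 0.0070.

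Inflammatory cytokine genes followed HL-60 too, with medians of −0.85, −0.87, 0.25 and 1.87 over 17 genes, of which the MOLM13 value was inside the range. The chemokines CCL2 and CXCL8 had 220 and 162 TPM in HL-60 and at most 3.84 TPM elsewhere, whereas IL32 had 870 TPM and IL1B 85.6 TPM in the library labelled MOLM13. Class I antigen presentation had medians of −1.23, −2.16, 0.86 and 1.46 over 13 genes, outside the range in every line. HLA-B was listed at 5.44, 0.22, 12.4 and 1144 TPM, HLA-C at 24.9, 3.11, 195 and 553 TPM and the immunoproteasome subunit PSMB8 at 6.36, 0.049, 155 and 198 TPM; HLA genes vary so much that reads of some alleles can fail to align. Of 11 class II genes, 3 were detected, none at 10 TPM, too few for a percentile. Mitochondrially encoded genes had medians of −0.22, −0.24, −0.01 and 0.50 over 13 genes, of which only HL-60 lay outside the range. MT-ND6 was listed at 1745, 1397, 2338 and 6232 TPM, and MT-ND3 at 6484, 1983, 6015 and 6548 TPM. HL-60 also had 269 genes at least 4-fold below every other line. The red cell ammonium channel RHAG was listed at 0 against 295 TPM or more, the serine protease PRSS21 at 0 against 96.5 TPM or more and the actin bundler FSCN1 at 0.54 against 198 TPM or more. Over all detected genes the HL-60 median log2 difference was −0.36 and that of the library labelled MOLM13 was 0.16, against 0.01 and 0.03 for the others, and random lists carry the same shift. The counts moved with the scaling. After median-ratio scaling HL-60 had 315 enriched and 208 depleted genes, and the library labelled MOLM13 had 350 and 113. Without the library labelled MOLM13 among the comparators HL-60 had 2.15 times as many enriched genes and 938 depleted ones.

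**Figure D2:**
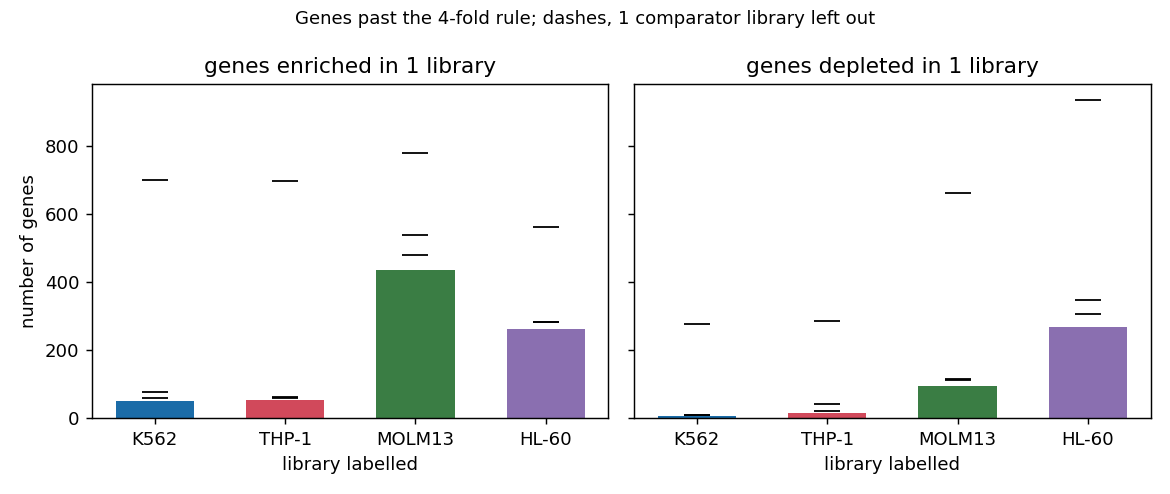
Number of genes (y axis) at least 4-fold above (left) or below (right) every other library, per library as labelled (bars), with dashes for the count when 1 of the comparator libraries is left out. The enriched counts are 51, 54, 436 and 262 and the depleted counts 6, 15, 96 and 269 for K562, THP-1, MOLM13 and HL-60; without the library labelled THP-1 the K562 counts are 701 and 277.

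Lists of growth and sugar use stayed inside the random range. Proliferation genes had medians of 0.06, 0.17, 0.11 and −0.15 over 28 genes and glycolysis genes −0.21, 0.16, −0.08 and 0.04 over 19 genes. Single members still differed. UBE2C, a mitotic ubiquitin-conjugating enzyme, was listed at 1.99, 1.24, 114 and 185 TPM in the order K562, THP-1, MOLM13, HL-60, cyclin D1 (CCND1) at 56.1, 27.9, 0.19 and 31.4 TPM, and hexokinase HK1 at 327, 302, 43.7 and 7.08 TPM. The glucose transporter SLC2A3 was listed at 169, 125, 26.4 and 12.4 TPM.

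Leukaemia driver genes had medians of −0.28, 0.03, 0.58 and −0.20 over 34 genes, below the range in K562 and above it in the library labelled MOLM13. CDKN2A, a cell-cycle inhibitor often lost in leukaemia, and its neighbour MTAP were listed at 0 in both K562 and the library labelled THP-1, and at 146 and 48.5 TPM in that labelled MOLM13 and 22.2 and 26.7 TPM in HL-60. MYC, a growth regulator, was highest in HL-60, at 952 TPM against 234, 274 and 467 TPM. The receptor kinase FLT3 was listed at 0, 0, 0.029 and 7.01 TPM. The signal transducer STAT5A was listed at 509, 494, 236 and 4.23 TPM, the progenitor factor GATA2 at 131, 107, 212 and 3.54 TPM, the granulocyte factor CEBPA at 1.74, 0.86, 40.2 and 211 TPM and the myeloid factor SPI1 at 31.9, 16.9, 17.5 and 279 TPM. RUNX1 was listed at 22.5, 35.6, 180 and 54.9 TPM, BCL2 at 4.14, 6.25, 50.4 and 19.6 TPM, and MECOM at 10.1, 12.5, 0 and 0 TPM.

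lncRNAs with a known micropeptide or a second function, the kind named by the series title, were mostly shared between the lines. Of 61 listed symbols 52 were in the files, 36 were detected (33, 34, 30 and 26 at 1 TPM or more in K562, THP-1, MOLM13 and HL-60) and 29 reached 10 TPM. Their median log2 difference was 0.16 in K562, 0.48 in the library labelled THP-1, −0.40 in that labelled MOLM13 and −0.35 in HL-60, above the range in the second and below it in the third; rescaled over coding genes, which keeps 7 of the 36, the THP-1 value was −0.21. GAS5, a growth-arrest lncRNA, was listed at 597, 824, 444 and 614 TPM, NORAD, which binds Pumilio proteins, at 152, 193, 151 and 108 TPM, TUG1 at 85.6, 124, 129 and 78.5 TPM and CYTOR at 128, 100, 40.6 and 30.2 TPM. MEG3 and UCA1 (100, 62.1, 0 and 0.13 TPM) separated the first pair from the others. LINC00689 did so at a lower level, at 13.1, 7.31, 0 and 0 TPM. NBDY, which encodes a decapping-complex micropeptide, was listed at 11.2, 2.11, 37.7 and 15.7 TPM, and PVT1, the neighbour of MYC, at 97.7, 56.0, 60.2 and 16.6 TPM. MEG3 is also on the haematopoietic list.

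lncRNAs of the HOX clusters had medians of 1.30, 0.63, −0.93 and −1.24 over 11 genes, above the range in K562 and below it in the libraries labelled MOLM13 and HL-60. HOTAIRM1, at the 3' end of the HOXA cluster, was listed at 38.9, 10.6, 5.88 and 9.25 TPM, HOXA-AS2 at 8.87, 1.18, 10.6 and 0.075 TPM and HOXB-AS3, which encodes a peptide and overlaps HOXB genes on the other strand, at 10.1, 4.28, 0 and 0 TPM. Hosts of small nucleolar RNAs had medians of 0.13, 0.49, −0.46 and −0.01 over 25 genes, above the range in the library labelled THP-1 and below it in that labelled MOLM13; SNHG5 was listed at 1401, 975, 253 and 112 TPM and SNHG4 at 112, 299, 41.1 and 156 TPM. MicroRNA hosts (medians −0.34, 0.31, −0.01 and −0.61 over 20 genes) and haematopoietic lncRNAs (0.10, 0.11, 0.09 and −0.71 over 24 genes) lay inside the range. MIR17HG, host of an oncogenic microRNA cluster, was listed at 60.7, 124, 15.6 and 19.9 TPM, and MIR155HG at 0.077, 0.056, 11.5 and 0.43 TPM. RP11-358M11.2, also called LINC00926, had 174 TPM in HL-60 and at most 1.88 TPM elsewhere.

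Among all detected lncRNA genes, 81 of 3234 were enriched in 1 line, or 2.505% (exact 95% interval 1.99 to 3.10%), against 667 of 13159 coding genes, or 5.07% (4.70 to 5.46%). Among coding genes matched on the highest TPM a median of 1.39% were enriched, with a middle 95% of 1.02 to 1.79%. The lncRNA share thus lay above that of matched coding genes; against all coding genes its direction depended on the detection limit, since at 5 TPM it was 7.58% against 5.91%. Without the library labelled THP-1, left out after the data were seen, the shares were 4.42% and 9.47%. For the 270 lncRNA genes without clone names it was 4.44%, within the matched range of 1.11 to 4.81%. The intervals treat genes as independent and cover counting error only.

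Exon coverage of the fusion partners asked whether the libraries held the rearrangements known for the lines, since a fusion transcript carries only part of each gene. The BCR and ABL1 coverage in K562 and in the library labelled THP-1 had the same shape: much of ABL1 after exon 1 and much of BCR up to exon 14. BCR exon 14 itself had a coverage of 302 and 350. ABL1 (chromosome 9, 130713946 to 130887675), a tyrosine kinase gene, had 55.8 times as much coverage over exons 2 onward as over exon 1 in K562 (95% counting interval 37.2 to 83.5) and 84.2 times in the library labelled THP-1 (49.6 to 143), against 8.15 and 7.29 times in those labelled MOLM13 and HL-60. BCR (chromosome 22, 23179704 to 23318037) had 0.101 and 0.0884 times as much coverage over exons 15 onward as over exons 1 to 13 in K562 and the library labelled THP-1, and 0.640 and 0.779 times in the others; by the median over exons the ratios were 0.199, 0.141, 1.16 and 1.10. Between exons 13 and 15 BCR coverage went from 491 to 106 in K562 and from 586 to 68.3 in the library labelled THP-1. In the library labelled MOLM13 it went from 474 to 469 and in HL-60 from 205 to 165. KMT2A (chromosome 11, 118436490 to 118526832), a histone methyltransferase gene, had ratios of 1.35, 1.48, 1.40 and 1.59. MLLT3 (chromosome 9, 20341665 to 20622543), its partner in THP-1 and MOLM13, had ratios of 7.38, 0.742 and 0.650 in K562, MOLM13 and HL-60 and no value in the library labelled THP-1, where the first exons had a coverage of 0. By the median over exons the MLLT3 ratios were 75.9, 3.94 and 2.06, so this gene gives no clear reading. The values are coverage by reads, not fusion reads, and the files hold no junctions.

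**Figure D3:**
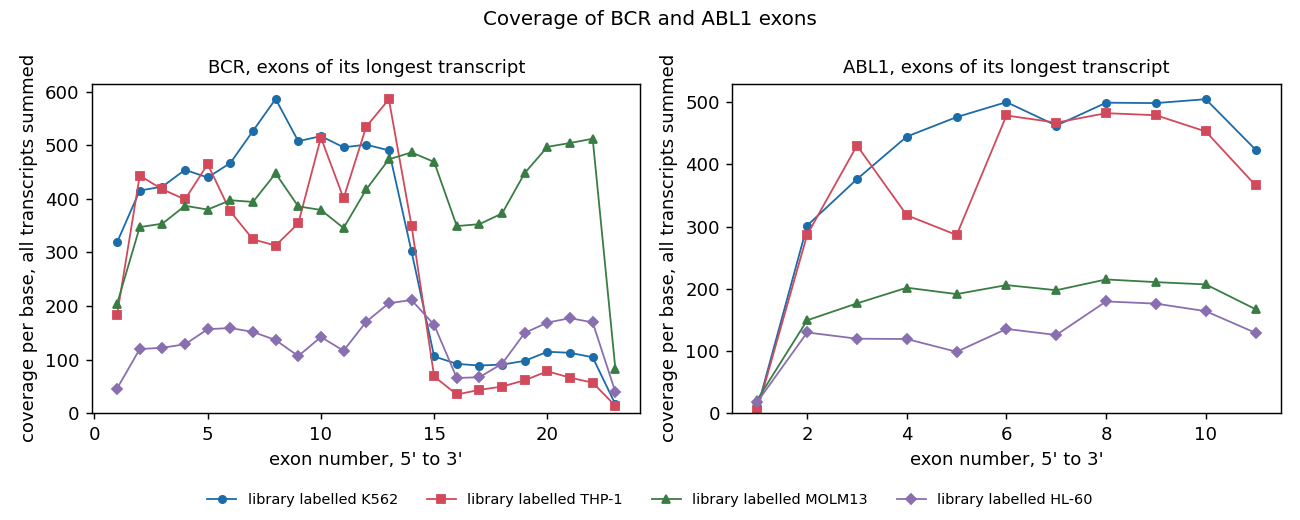
Read coverage per base, summed over transcripts (y axis), of each exon (x axis) of the longest transcript of BCR (left) and ABL1 (right); each line is 1 library as labelled. BCR coverage goes from 491 to 106 and from 586 to 68.3 between exons 13 and 15 in the libraries labelled K562 and THP-1, and from 474 to 469 and from 205 to 165 in those labelled MOLM13 and HL-60.

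Which transcript dominated a gene differed between libraries in 428 of 6149 genes (6.96%), 425 of them coding and 3 lncRNA, by a share difference of at least 50 points. NCOA6, a nuclear receptor coactivator, had 97.8% of its TPM in ENST00000374796.6 in HL-60 and at most 0.47% in the other lines. WDR1, an actin disassembly factor, had 84.8%, 96.2% and 86.4% in ENST00000499869.6 in K562, THP-1 and HL-60, and 0 in the library labelled MOLM13. SPC24, a kinetochore subunit, had 87.5%, 88.7% and 92.2% in ENST00000592540.5 in the libraries labelled K562, THP-1 and MOLM13 and 0 in HL-60. The nuclear transport receptor XPO4 had 49.1%, 94.1%, 88.1% and 0 in ENST00000400602.2, C1orf27 had 0, 0, 51.7% and 91.8% in ENST00000287859.10, and MID1IP1, a regulator of lipid synthesis, had 3.72%, 42.1%, 98.5% and 52.7% in ENST00000336949.6. Between the libraries of a pair, 148 genes differed for K562 and THP-1, against 99 to 172 for the other pairs. The pair closest in expression thus switched as often as others, so the count cannot be read as differences between lines. Shares of transcripts that overlap are estimates, and an exact 0 can be a failed one; with at least 30 points the count was 1237 and with at least 70 points 86.

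Runs of neighbouring genes silent in a line, whether or not other lines shared the silence, were counted next. Among 11249 coding genes in genome order, each at 5 TPM or more in at least 1 line and called silent under 0.5 TPM, runs of 3 or more numbered 28, 26, 22 and 40 in K562, THP-1, MOLM13 and HL-60, and the highest of 1000 shuffled orders gave 9, 10, 15 and 21. K562 and the library labelled THP-1 shared 62 genes in such runs (of 104 and 98), the libraries labelled MOLM13 and HL-60 shared 57 (of 95 and 166), and other pairs shared 12 to 14. The longest in K562 held 7 genes around the lectin receptors CLEC12A and CLEC7A on chromosome 12 (9852984 to 10191801), and 6 zinc finger genes on chromosome 19 (19900913 to 20661596). In the library labelled THP-1 they were 6 genes of the same lectin cluster and 6 on chromosome 10 (88822132 to 89414557), including FAS, the lysosomal lipase LIPA and IFIT2. The libraries labelled MOLM13 and HL-60 were silent over 12 GAGE and PAGE1 genes on chromosome X (49322057 to 49695993) and over 10 and 11 globin and olfactory receptor genes on chromosome 11. Chosen after their values were seen, runs of 5 genes with MTAP and CDKN2A on chromosome 9 (21329671 to 25678440) occurred in both K562 and the library labelled THP-1, and 1 of 4 genes with USP22 on chromosome 17 (20999593 to 21315240) in the library labelled MOLM13.

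Windows of 25 neighbouring genes gave the regional extremes. In K562 the highest lay on chromosome X (49175264 to 52520803, median log2 difference 3.78), led by GAGE12G, GAGE2E and GAGE12F, and the lowest on chromosome 19 (57363511 to 57889074, −2.06) over zinc finger genes such as ZNF530 and ZNF548. The library labelled THP-1 was highest over the globin locus on chromosome 11 (3339261 to 5678434, 2.04) and lowest on chromosome 15 (30083053 to 34343177, −1.23), where GOLGA8N and GOLGA8O belong to a family of near-identical copies. That labelled MOLM13 was highest over zinc finger genes on chromosome 19 (57466663 to 58118427, 1.89), ZIK1 and ZNF256 among them, and lowest over the same GAGE window on chromosome X (−1.83). HL-60 was highest on chromosome 5 (148825245 to 151492381, 1.19), with the membrane-binding gene ANXA6 at 87.8 TPM, and lowest on chromosome 10 (15077523 to 22714555, −1.94), where VIM, the filament protein of mesenchymal and blood cells, was listed at 690, 331, 4.82 and 13.2 TPM. Windows of 50 genes moved the highest window of K562 and of the library labelled THP-1 to chromosome 6 and the lowest of that labelled MOLM13 to chromosome 7; after median-ratio scaling the lowest of HL-60 was on chromosome X and the highest of the library labelled MOLM13 lay elsewhere on chromosome 19, from 19900913.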

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

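The comparators without both the libraries labelled THP-1 and MOLM13, and the lncRNA share without that labelled THP-1, were chosen after the data were seen; all other alternatives were fixed before. Values are in the order K562, THP-1, MOLM13, HL-60 unless lines are named, and where no construction is given the cause was not tested. Counts of genes past a fold depend on the fold, the minimum and the comparators by construction. The FPKM setting kept the same minimum and pseudocount on values that run below TPM, so by construction it is a stricter limit. Genes at a few TPM and those with shared sequence are limited by depth and by read assignment.

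Enriched genes numbered 95 in K562 and 99 in THP-1 with a minimum of 1 TPM; 203, 197, 1139 and 449 at 2-fold; 23, 30 and 252 at 8-fold in the first 3; and 29, 17, 239 and 174 on FPKM. They numbered 697 in THP-1 without K562, 701 in K562 without THP-1, 5.6e+02 (rounded to 2 digits) in HL-60 without MOLM13 and 782 in MOLM13 without HL-60. Without both THP-1 and MOLM13 they were 1287 in K562 and 665 in HL-60. Depleted genes numbered 17, 35, 179 and 440 with a minimum of 1 TPM; 52, 71, 233 and 771 at 2-fold; 9 in THP-1 and 147 in HL-60 at 8-fold; 3, 6, 52 and 107 on FPKM; and 24 in THP-1 rescaled over coding genes. They numbered 285 in THP-1 without K562, 277 in K562 without THP-1, 10 in K562 and 938 in HL-60 without MOLM13, and 11 in K562, 42 in THP-1 and 663 in MOLM13 without HL-60. Without both THP-1 and MOLM13 they were 665 in K562 and 1287 in HL-60. The other 27 enriched and 18 depleted counts stayed within 1.5 times. Among them, after median-ratio scaling the enriched counts were 51, 52, 350 and 315 and the depleted counts 6, 16, 113 and 208. HL-60 then had more enriched than depleted genes, the reverse of its main counts of 262 and 269. Of values of single named genes, 12 enriched and 5 depleted no longer passed under an alternative, and 451 and 163 kept their side.

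Over genes at 10 TPM the Spearman correlations were 0.925 for K562 and THP-1, 0.662 for K562 and MOLM13, 0.646 for K562 and HL-60, 0.650 for THP-1 and MOLM13, 0.666 for THP-1 and HL-60 and 0.733 for MOLM13 and HL-60. Over all genes above 0 they were 0.889 for K562 and THP-1, 0.730 for K562 and HL-60 and 0.781 for MOLM13 and HL-60. K562 and THP-1 had the highest value in each of these settings; the pseudocount cannot move a rank correlation.

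Lists below the range numbered 5 in HL-60 when rescaled over coding genes and 4 in K562 without HL-60, and lists above it 5 in THP-1 without MOLM13. Of values of single lists, 677 kept their direction and side, 38 passed out of the range, 35 came inside it, and 10 lost their direction. These were the dual-function lncRNAs in THP-1 (−0.21 rescaled over coding genes, which leaves fewer members), megakaryocyte genes in MOLM13 (4.47 with members at 10 TPM), immediate-early genes in HL-60 (−0.22 without K562, at percentile 71.0 of the random lists), interferon genes in HL-60 (0.24 without MOLM13), and without HL-60 the azurophil (0) and monocyte (0.0070) lists in K562, both lists in THP-1 (0 and 0), and the late neutrophil (0) and NADPH oxidase (0) lists in K562. HL-60 is the library in which these last 4 lists were highest.

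The lncRNA share enriched was 4.44% for genes without clone names, inside the matched range. It stayed above that range at 1.14% with detection at 0.1 TPM, 7.58% at 5 TPM, 2.72% with a pseudocount of 0.1 TPM and 4.42% without the library labelled THP-1, and at 5 TPM it also exceeded the 5.91% of all coding genes. KMT2A ratios from the highest transcript were 1.46 in K562, 1.34 in MOLM13 and 1.38 in HL-60. By the median over exons the ratios were 0.199, 0.141, 1.16 and 1.10 for BCR, 1.08, 1.04, 1.07 and 1.04 for KMT2A, and 75.9 in K562, 3.94 in MOLM13 and 2.06 in HL-60 for MLLT3, which has no value in THP-1. Transcript switches numbered 1237 at 30 points, 86 at 70 points and 916 with a minimum of 1 TPM. Silent runs numbered 13 in K562 and 23 in HL-60 under 0.1 TPM, and 6, 5, 4 and 7 with 5 or more neighbours; each exceeded the highest shuffled order. With 50 genes the highest windows were 1.54, 1.43, 1.61 and 0.982 and the lowest −1.53, −0.81, −1.27 and −1.82; after median-ratio scaling they were 3.76, 1.99, 1.65 and 1.52, and −2.02, −1.28, −1.85 and −1.81.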

Other observations

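Of the 6 tests below, the 5 on the libraries labelled THP-1 and MOLM13 were chosen after the result was seen; the one on OR51B5 was written before.

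Genes listed at 0 in 1 library while each other library had 20 TPM or more set the lines apart in another way. There were 17 such genes in the library labelled MOLM13, 14 in HL-60 and none in K562 or that labelled THP-1. Genes listed at 0 in both K562 and the similar library labelled THP-1, such as CDKN2A and MTAP, cannot count. The names here were chosen after their values were seen. In the library labelled MOLM13 they included PITX1, a limb and pituitary homeobox factor (70.4, 142 and 176 TPM in K562, THP-1 and HL-60), PHGDH, which starts serine synthesis (43.0, 89.3 and 57.9 TPM), IGF2BP1, a fetal RNA-binding protein (92.3, 78.4 and 28.8 TPM), and the receptor gene TNFRSF1B (38.1, 40.2 and 44.8 TPM). In HL-60 they included TAL1, a regulator of blood stem and erythroid cells (39.1, 55.6 and 29.7 TPM in K562, THP-1 and MOLM13), the potassium channel KCNH2 (284, 274 and 23.7 TPM) and the activation antigen CD69 (59.6, 37.1 and 32.3 TPM). HL-60 was also silent over 8 neighbouring HOXB genes (chromosome 17, 48540894 to 48633572) and the library labelled MOLM13 over 5 of them. An exact 0 can be a failed estimate.

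For the closeness of the library labelled THP-1 to the K562 library, K562 RNA mixed into THP-1 RNA would bring every K562 transcript at that share, but 4 genes at 50 TPM or more in K562 lay under 0.05 of their K562 level (SRGN, GAGE12J, CD3D and MEG3, at 0.025 to 0.048), while the median ratio over erythroid genes was 1.48. An erythroid programme alone in unrelated cells would leave BCR coverage as in HL-60, but the HL-60 ratio was 8.80 times that of the library labelled THP-1. A wrong label on this library met its test, which used values already seen, so meeting it adds no support beyond them. The ABL1 ratio was 10.3 times the higher of those labelled MOLM13 and HL-60, and the monocyte list lay at percentile 0. That percentile depended on HL-60 as a comparator (the median was 0 and inside the range without it). The low level itself did not depend on it. Of 31 listed monocyte genes, 3 reached 1 TPM in the library labelled THP-1, against 5, 4 and 22 in K562, MOLM13 and HL-60. ABL1 and BCR coverage thus carry the reading that the library may come from cells with the BCR-ABL1 fusion. Which cells these were stays open, and the values cannot tell a wrong label from a culture of other cells. The mixing test covers RNA like that of this K562 library, not that of another culture with the fusion. Apart from the erythroid programme, no biological explanation was tested, since the labels give none.

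The library labelled MOLM13 had little FLT3 (0.029 TPM), MEIS1 listed at 0, which can be a failed estimate, and high CD3D (536 TPM) and CD7 (120 TPM). It also had 297 TPM of the progenitor marker CD34 and 736 TPM of RHAG, the red cell ammonium channel gene. Of 27 erythroid genes, however, 20 were at least 2-fold lower there and 4 higher. Lymphocytes mixed into the culture would bring other lymphocyte genes, but CD2, CD5, CD8A, IL7R, MS4A1, CD79B and PAX5 had a median of 0.0564 TPM and at most 0.137 TPM. Targets of KMT2A fusions went the way the label says, with a median log2 difference of 0.81, above the random range, and HOXA9 at 139 TPM, whereas the monocyte list went against it, with a median of −1.07 below the range (inside it without HL-60 as a comparator) and CD14 at 0.29 TPM. A wrong label on this library cannot be told apart from a true one by MLLT3 coverage: its ratio was 1.14 times that of HL-60 by the mean, 1.91 times by the median over exons and 1.04 times by the highest transcript. The mean is weighted by length and rests mostly on exon 11, with a coverage of 25.7 in this library. From exon 5 to exon 8 MLLT3 coverage went from 90.3 to 271 there and from 19.5 to 24.85 in HL-60. It also rose in K562, from 0.81 to 46.1, so the rise is not particular to this library. The KMT2A ratio of 1.40 lay between those of K562 (1.35) and HL-60 (1.59) and did not set this library apart. Few reads on MLLT3 in HL-60 (2.34 TPM) and the disagreement of the MLLT3 summaries keep the label open. No biological explanation was tested, since the labels give none.

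OR51B5, an olfactory receptor gene, was listed at 415 TPM in the library labelled THP-1 and at 7.52 TPM in K562. Globin reads assigned to exons that overlap globin exons could have given this, but 0.696% of its covered bases lay in such exons. A single exon (chromosome 11, 5340325 to 5341362) held 49.5%. That exon lies within the span of HBE1 but outside globin exons, and reads from globin introns were not tested. Where this transcription starts stays open, since strand and junctions are not in the files.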
